A study of Mus musculus with 2 samples.

How the data were processed

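RM-1 cells, a mouse prostate cancer line, had been grown under the skin of C57BL/6 mice, and the tumours were taken on day 10 of vehicle or of RP-6306, an inhibitor of the kinase PKMYT1. Per the labels' protocols, CD45+ cells were sorted from the dissociated tumours, mixed with tumour cells at 3 to 1, and made into droplet single-cell libraries with the SeekOne DD kit. The design text names a pair of mice without saying whether each group came from 1 of them. There was 1 library per group, so no replicate check and no test between groups was possible.

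The deposited matrices hold counts: whole numbers of unique molecular identifiers (UMIs) per gene and cell barcode, not normalized. Per the submitters' processing notes, Cell Ranger 2.1.1 and the genome build mm10 were used, without their roles. How barcodes were chosen as cells is not given in the sources used here. Both matrices list 32285 genes. The vehicle matrix held 17313 barcodes and 135415063 UMIs, and the RP-6306 matrix held 15909 barcodes and 158073632 UMIs. Gene IDs were matched to GENCODE for GRCm38, the assembly of mm10, and 32158 of the 32285 IDs were found there.

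Everything from here on was computed for this work from the deposited counts, with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9. Cells needed at least 500 UMIs, at least 300 genes and at most 15% mitochondrial UMIs. Scrublet, run per library, called 3 vehicle and 1 RP-6306 barcodes as doublets at its automatic threshold, which is below 0.5% of cells, so the top 6% of scores per library were removed instead (1038 vehicle and 984 RP-6306 barcodes). This left 16070 and 14884 cells, with medians of 3108 and 2842 UMIs. Such a score does not find all doublets, and droplets that carry genes of more than 1 lineage remained.

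The cells of both libraries were clustered together without batch integration (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1), and the T and NK and the myeloid clusters were clustered again. Clusters were named from markers fixed before the data were examined. The scoring rule that turns markers into names was revised after its first output, cell numbers per library included, had been seen, and the first version is kept as an alternative. Clusters that mixed lineages, had low UMIs or lacked leading markers stayed unnamed (24.2% of vehicle and 12.9% of RP-6306 cells). Leading genes of B cluster 12, of tumour cluster 3 and of T clusters T7, T8 and T13 held more markers of another class than of their own, so B cells and other T cells are given by cluster number, and tumour values are given for clusters 3, 6 and 7 together and by number.

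Shares carry exact Clopper-Pearson 95% intervals. UMIs were summed per class and library and scaled to CPM. Log2 ratios, RP-6306 over vehicle, used CPM + 1, and their exact conditional binomial 95% intervals were computed without this pseudocount. All intervals cover counting error only. Coordinates are 1-based gene bounds on GRCm38, and UMIs were counted per gene. A class needed 50 cells and a gene 20 UMIs over both libraries. Neutrophil-like and dendritic cell-like cells were under 50 cells in at least 1 library, so their expression was not compared. Each gene list, fixed per class before the data were examined, has the median log2 ratio of its measured members and its percentile among 10000 random lists of the same size matched on mean expression, which describes these libraries only. Cell cycle phase was called after thinning each cell to 2000 UMIs. The expression step was tested on simulated data with 200 changed genes: among tumour-like cells it gave the right direction for 100.0% of genes changed 2-fold and for 99.0% of those changed 1.5-fold, and 95.5% of intervals held the true ratio. The simulated sums held counting error only, as the intervals assume, with no spread between cells or libraries. This coverage was therefore set by the simulation and does not bear on genes whose UMIs lie in few cells.

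Named genes follow a rule set before the data were examined. In tumour-like, CD8 T-like, NK-like and macrophage and monocyte-like cells these were the 12 highest and 12 lowest log2 ratios among genes with at least 50 CPM and 50 UMIs in the library where they were higher, and the 5 highest and lowest elsewhere. Up to 4 members per list with the largest ratios, and a short fixed set that includes Pkmyt1, Wee1, Cdk1, Ccnb1, Cd274, Gzmb and Prf1, were named too. Mitochondrial, ribosomal, hemoglobin and antigen receptor genes and predicted genes without a gene symbol of their own were left out. Some genes that the rule takes are not reported here. A further set, limited to genes with under 20% of their level from free tumour RNA, was chosen after seeing the data. This part of a gene's level was computed for the library where the gene was higher. Free tumour RNA in each leukocyte class was estimated, by a method also chosen after seeing the data, as the 5% quantile, over genes above 100 CPM in tumour-like cells, of the level in the class divided by the level in tumour-like cells of the same library. By construction 5% of these genes lie below the estimate, so it may be too high. In RP-6306 macrophage and monocyte-like cells it was 5.33%. Krt18 was at 5.34 CPM there and at 354 CPM in tumour-like cells, a smaller part than this estimate.

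Alternatives set before the data were examined changed the mitochondrial limit, the UMI and gene minimum, doublet removal, clustering resolution, joint clustering, naming by cluster, scaling, the pseudocount, the UMI minimum per gene, the weight of cells and the depth. A share counted as the same where the alternative lay within the main counting interval. A list counted as the same where its median moved by less than the half-width of the range of random lists, and a gene where its ratio moved by less than the half-width of its counting interval. A change of sign counted as reversed only for a gene or share whose interval excluded a log2 ratio of 0 and for a list outside the central 95% of random lists.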

Results

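The study asked how the PKMYT1 inhibitor RP-6306 changes RM-1 prostate tumours and the immune cells in them. PKMYT1 is a kinase that holds back CDK1 before mitosis. Single-cell transcriptomes were measured in 1 vehicle and 1 RP-6306 library on day 10 of treatment, so each difference below is between 2 libraries, with no replicate check, and intervals cover counting error only. After filtering, 16070 vehicle cells held 127097785 UMIs and 14884 RP-6306 cells held 146902214 UMIs. RP-6306 blocks the protein, so the Pkmyt1 transcript does not check the labels.

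Among leukocytes, CD4 T-like cells made up a larger part of the RP-6306 library and NK-like cells a smaller one. CD4 T-like cells were 16.4% (95% interval 15.6 to 17.1, 1529 cells) of 9337 named leukocytes in the vehicle library and 27.5% (26.6 to 28.4, 2710 cells) of 9861 in the RP-6306 library, a 1.68-fold difference. NK-like cells, innate killers of tumour cells, were 4.40% (3.99 to 4.84, 411 cells) and 1.45% (1.22 to 1.71, 143 cells), 3.04-fold lower. Regulatory T-like cells, which restrain other T cells, were 1.9599% (1.69 to 2.26) and 1.26% (1.05 to 1.4975), and gamma delta T-like cells were 0.589% (55 cells) and 0.254% (25 cells). The gamma delta T-like shares were 2.91% and 1.13% at the lower clustering resolution and 3.68% and 1.87% when cells were assigned by their own marker scores, and 51 and 0 cells were so named with each library clustered on its own. CD8 T-like cells, the main cytotoxic T cells, were 24.2% (23.3 to 25.1) and 22.1% (21.3 to 22.9), and macrophage and monocyte-like cells were 5.22% (4.77 to 5.69) and 4.97% (4.55 to 5.42).

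Most vehicle CD4 T-like cells lay in cluster T1 and most RP-6306 ones in cluster T2, which is led by Cd4 and Il7r among others. T1 was 12.9% (1206 cells) and 12.8% (1262 cells) of named leukocytes, and T2 was 3.46% (323 cells) and 14.7% (1448 cells). Il7r differed between the libraries, and how far this sets the size of T2 was not tested. Some clusters are compared by number. B cluster 0 was 34.1% and 32.5% of named leukocytes and B cluster 12 was 3.52% and 2.56%. T cluster T7, with NK receptor genes, was 2.29% and 1.33%, T8, with Gzmk and Ctla4, was 2.29% and 0.862%, T9 was 1.63% and 1.04%, and T13 was 0.407% and 0.314%. T6, led by Ifit3, Ifit1 and Isg15, was 1.92% (1.65 to 2.22, 179 cells) and 2.94% (2.62 to 3.29, 290 cells). Interferon-stimulated genes, which lead this cluster, were lower in tumour-like (median log2 ratio -0.37) and macrophage and monocyte-like cells (-0.65) of the RP-6306 library. In regulatory T-like cells their median was higher (0.33). T6 lies outside the CD4 T-like and CD8 T-like classes, so the interferon medians of those classes leave out its cells. An unnamed cluster with T and B cell genes mixed, led by Ctla4, Ikzf2, Il2ra and Gzmb as regulatory T cluster T10 is, held 2.89% and 1.24% of all cells and is in none of these shares. Neutrophil-like cells (46 and 39) and dendritic cell-like cells (57 and 49) were few. The sort and the 3 to 1 mix set the tumour share, which was 17.7% and 20.9% of all cells. It leaves out an unnamed cluster with low UMIs that scored highest for tumour markers. This cluster held 10.7% of vehicle and 1.77% of RP-6306 cells, so which library had the higher tumour share depends on leaving it out. When cells were assigned by their own marker scores, the log2 ratio of CD8 T-like cells went from -0.13 to 0.09 and that of regulatory T-like cells from -0.64 to -0.25. With the first version of the naming rule the log2 ratio of CD4 T-like cells was 1.91 in place of 0.75, that of CD8 T-like cells 0.01 and that of regulatory T-like cells -1.11, so the sizes of these shares depend on how clusters were named, and the tumour share went from 0.24 to 0.0551 with at least 1000 UMIs per cell.

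**Figure D1:**
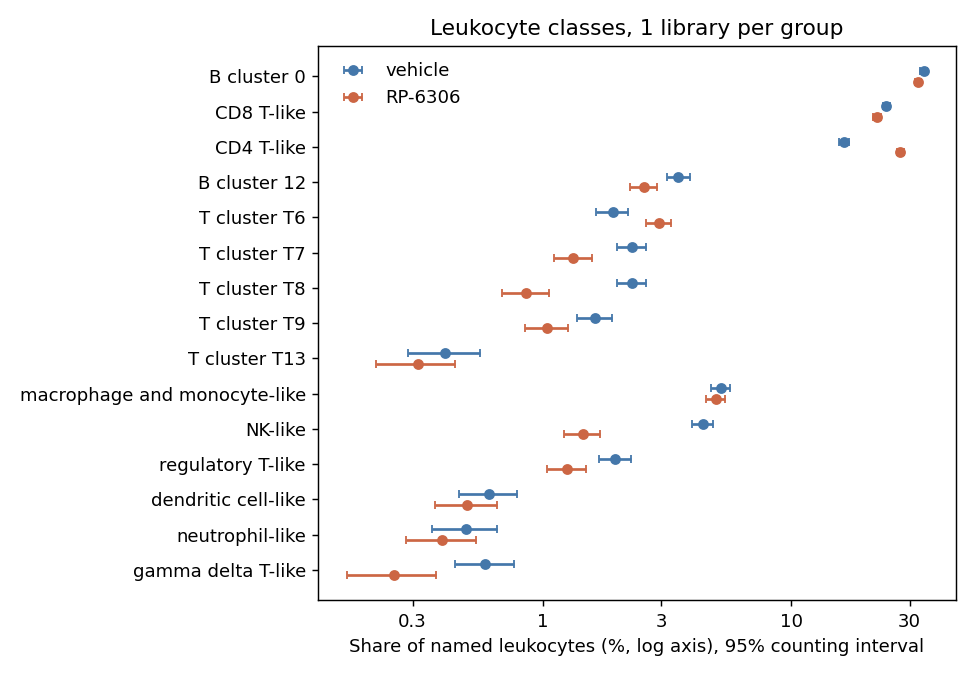
Shares of leukocyte classes, and of the B clusters (0 and 12) and T clusters (T6, T7, T8, T9 and T13) that are compared by number, among named leukocytes (%, log axis) in the vehicle and RP-6306 libraries, with exact 95% counting intervals as bars. CD4 T-like cells lie at 16.4% and 27.5% and NK-like cells at 4.40% and 1.45%.

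In tumour-like cells (2847 vehicle, 3106 RP-6306), cell cycle genes were higher and interferon genes lower in the RP-6306 library. All 43 measured S phase genes (median log2 ratio 0.38) and all 54 G2/M genes (0.43) were higher, as were 16 of 17 PKMYT1 pathway genes (0.49) and 12 of 13 histone genes (0.53), each above all of the matched random lists. Ccne1, the cyclin of S phase entry, was at 13.2 and 25.02 CPM, Ccnb1, the mitotic cyclin, at 29.4 and 47.7 CPM (log2 0.68, interval 0.63 to 0.77), Cdk1 at 67.4 and 96.0 CPM and Plk1, a mitotic kinase, at 55.8 and 90.3 CPM. Rrm2, a subunit of ribonucleotide reductase, was at 97.2 and 171 CPM (0.81, 0.78 to 0.85). Pkmyt1 itself (chromosome 17, 23726336 to 23736735 in GRCm38) was at 12.98 and 14.07 CPM and Wee1 at 22.999 and 24.98 CPM. Within clusters 6 and 7 the log2 ratio of Pkmyt1 was -0.15 and -0.17, and within cluster 6 that of Wee1 was -0.31.

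Phase calls at 2000 UMIs per cell put 42.7% (40.9 to 44.5, 1211 of 2837) of vehicle and 57.0% (55.3 to 58.8, 1765 of 3095) of RP-6306 tumour-like cells in S or G2/M. Without thinning the shares were 39.6% and 55.9%. These calls are read beside the summed levels, since 61.9% and 59.4% of CD8 T-like cells, whose S phase list was at 0.02, were also called S or G2/M. The differences in the lists were smaller within the tumour clusters: within clusters 3, 6 and 7 the G2/M list was at 0.05, 0.00 and 0.03, the S phase list at 0.27, 0.02 and 0.25, the PKMYT1 pathway at 0.10, 0.04 and 0.13, and the histones at -0.10, 0.27 and -0.23. Clusters 6 and 7 are led by S phase histones and by mitotic genes.

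Interferon and antigen presentation genes were lower in the RP-6306 tumour-like cells. Of 33 interferon-stimulated genes 31 were lower (median -0.37), as were 24 of 26 genes induced by interferon gamma (-0.33) and 19 of 22 MHC class I genes (-0.24), all below the random lists. Zbp1, a nucleic acid sensor, was at 18.1 and 9.01 CPM, Gbp2, an interferon-induced GTPase, at 42.8 and 23.02 CPM (-0.87, -0.97 to -0.82), Tap1, a peptide transporter, at 89.3 and 69.3 CPM, and H2-K1, a class I heavy chain (chromosome 17, 33996017 to 34000347), at 1220 and 900.2 CPM (-0.44, -0.45 to -0.43). Within clusters 3, 6 and 7 the interferon-stimulated list was at -0.33, -0.36 and -0.23, the interferon gamma list at -0.36, -0.17 and -0.38, and the class I list at -0.15, -0.25 and -0.23. With a pseudocount of 10 CPM the interferon-stimulated and interferon gamma lists were at -0.17 and -0.18.

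Genes of matrix, stress and metabolism were also compared. The epithelial-mesenchymal list was at -0.15, with Fn1, fibronectin, at 496 and 327 CPM, beside sums of 332 and 285 CPM for fibroblast and 117 and 96.2 CPM for endothelial markers, and the unfolded protein list at -0.14, with Atf3, a stress transcription factor, at 313 and 189 CPM. The hypoxia list was at -0.12, with Ndrg1 at 368 and 249 CPM. These 3 lists lay below the central 95% of random lists. The hypoxia and unfolded protein lists turned to 0.04 and 0.01 within cluster 3. Androgen response was at -0.13, cytosolic DNA sensing at -0.12, checkpoint ligands at -0.11, chemokines at -0.08, p53 targets at -0.03, oxidative phosphorylation at 0.11 and NKG2D ligands and death receptors at 0.13. Over all tumour-like cells only androgen response (percentile 1.65) of these lay outside the central 95% of random lists. Within clusters 3, 6 and 7 cytosolic DNA sensing was at -0.20, -0.29 and -0.27, each below that range. Also outside it were p53 targets within cluster 6 (-0.11), chemokines within cluster 7 (-0.21) and oxidative phosphorylation within clusters 6 and 7 (0.11 and 0.10). Among the most different single genes, Sele, E-selectin, was at 59.1 and 120 CPM (1.01, 0.98 to 1.07) and Lgals7, a galectin, at 97.4 and 173 CPM. Cp, ceruloplasmin (chromosome 3, 19957054 to 20009145), was at 107 and 39.5 CPM (-1.42, -1.49 to -1.38), and the chaperones Clu, Cryab and Hspb1 at 129 and 51.0, 59.98 and 23.6, and 242 and 109 CPM. Fosb, an immediate early gene, was at 543 and 247 CPM. The dissociation stress list summed to 10361 and 9904 CPM in these cells.

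**Figure D2:**
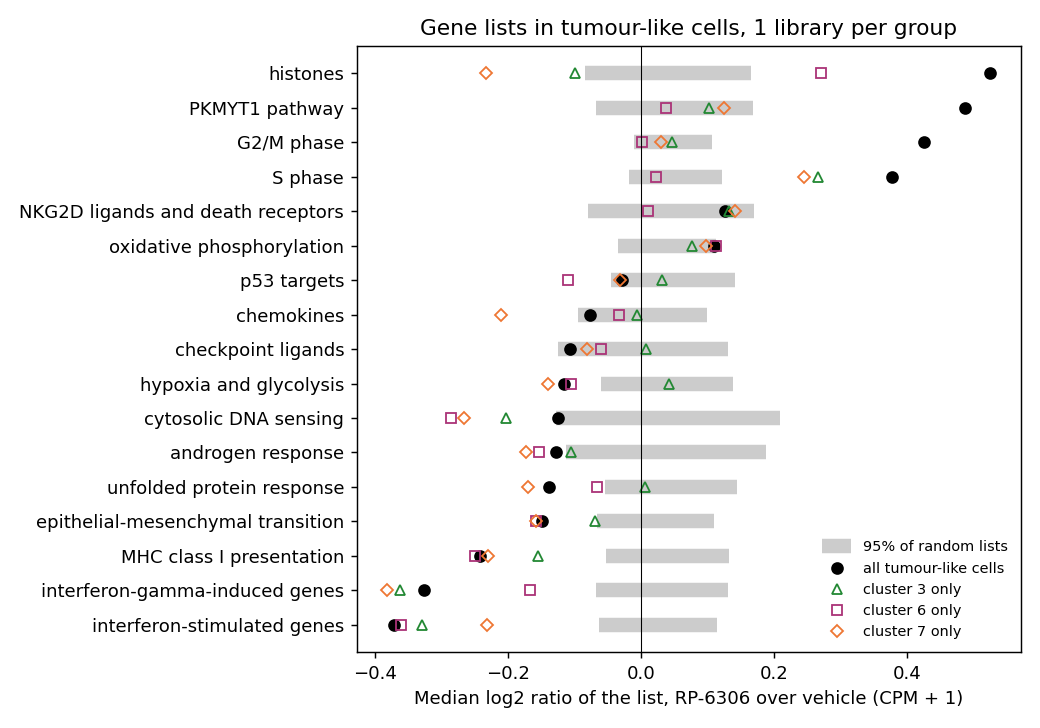
Median log2 ratio (RP-6306 over vehicle, CPM + 1) of each fixed gene list in tumour-like cells. Black points are all cells, open symbols are clusters 3, 6 and 7 alone, and grey bars span the central 95% of random lists. The G2/M list lies at 0.43 in all cells and at 0.05, 0.00 and 0.03 within the clusters, and the interferon-stimulated list at -0.37 and at -0.33, -0.36 and -0.23.

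Macrophage and monocyte-like cells (487 and 490) had more alternative activation and chemokine transcripts and fewer interferon transcripts in the RP-6306 library. The alternative macrophage list was at 0.62 (17 of 22 higher), with Mrc1, the mannose receptor (chromosome 2, 14229392 to 14332057), at 480 and 1370 CPM (1.51, 1.43 to 1.59, or -2.26 in monocyte clusters) and Stab1, a scavenger receptor, at 23.8 and 88.6 CPM. The chemokine list was at 0.68 (14 of 18 higher), with Ccl2 and Ccl7, which attract monocytes, at 318 and 888 and at 145 and 483 CPM, and Ccl17, a leading gene of dendritic clusters M6 and M12, at 4 and 270 UMIs in 3 and 11 cells, of which 1 RP-6306 cell held 46.7%. Its lower members were Ccl5 (42.1 and 5.56 CPM), Cxcl9, Cxcl10 (218 and 149.96 CPM) and Ccl24 (411 and 165 CPM). The inflammatory macrophage list was at 0.35 (11 of 18 higher, mean 0.15), or -0.17 within cluster M3, with Il6 at 14.5 and 48.9 CPM and Ccl5 and Cxcl9 among its lower members. Of 31 interferon-stimulated genes 30 were lower (-0.65), and the interferon gamma list was at -0.41. Rsad2, an antiviral enzyme, was at 81.6 and 14.5 CPM (-2.42, -2.91 to -2.10), with 53.8% of its RP-6306 UMIs in 1 cell, and Cxcl9, which attracts T cells, at 193 and 74.8 CPM (-1.36, -1.57 to -1.17).

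These differences were not alike in macrophage and monocyte clusters, and the 2 libraries drew on different clusters. In macrophage clusters alone the interferon-stimulated and interferon gamma lists were at -0.89 and -0.82, and in monocyte clusters alone they were at 0.11 and 0.49. The alternative macrophage and chemokine lists were at 0.31 and 0.49 in macrophage clusters, and at 0.14 and 0.26 in monocyte clusters. By single cluster the alternative list was at 0.11, -0.01, -0.35 and 0.18 in M0, M1, M2 and M3, in none of them above the central 95% of random lists. The chemokine list was at 0.27, 0.28, 1.00 and -0.07 there, above that range in M2 only. How far the mix of clusters sets the values of these lists over all cells was not tested. The monocyte cluster M1 held the most vehicle cells of the class, and the macrophage cluster M0 the most RP-6306 cells. Macrophage cluster M3 is led by Lyz2, Cxcl9 and Cxcl10 and cluster M4, with 30 and 83 cells, by Mrc1 and complement genes, so these genes both define clusters and differ between the libraries. MHC class II was at 0.09, checkpoint ligands at -0.07 (mean 0.19) and hypoxia at -0.10, and at 2000 UMIs per cell checkpoint ligands were at 0.22 and hypoxia at 0.06. Cd274, which encodes PD-L1, was at 211 and 198 CPM. The dissociation stress list summed to 7969 and 10446 CPM, macrophage markers to 4632 and 7340, neutrophil markers to 4802 and 6561, platelet markers, which share Pf4 with the macrophage set, to 131 and 265, and fibroblast markers to 22.8 and 6.45 CPM.

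**Figure D3:**
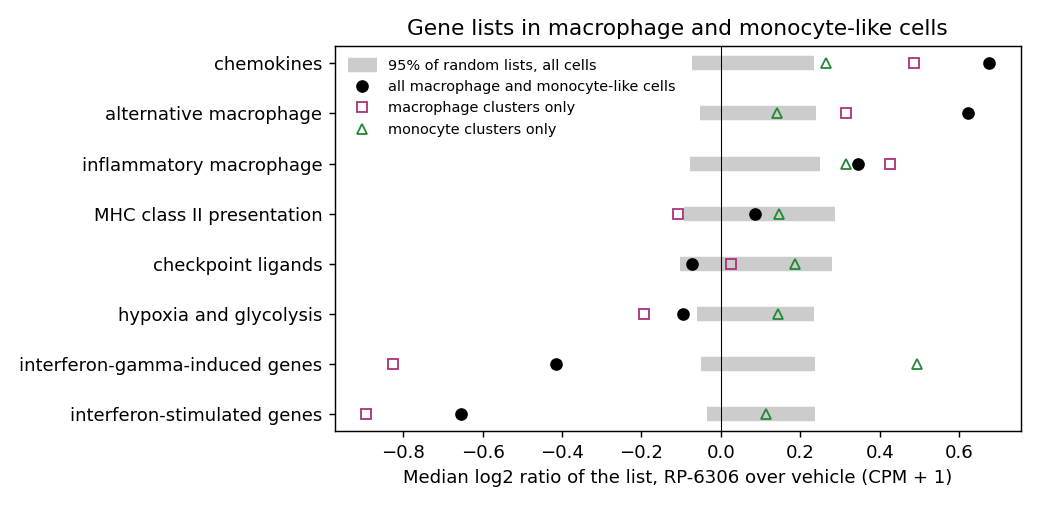
Median log2 ratio (RP-6306 over vehicle, CPM + 1) of each list in macrophage and monocyte-like cells. Black points are all cells, open squares macrophage clusters, open triangles monocyte clusters, and grey bars the central 95% of random lists. The interferon-stimulated list lies at -0.65 in all cells, -0.89 in macrophage clusters and 0.11 in monocyte clusters.

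CD8 T-like cells of the RP-6306 library had higher levels of genes of naive and memory T cells. This list was at 0.22 (13 of 16 higher), with Il7r, the survival receptor for interleukin 7 (chromosome 15, 9505788 to 9530176), at 742 and 1216 CPM (0.71, 0.66 to 0.76), Ccr7, a lymph node homing receptor, at 290 and 460 CPM and Klf2, a regulator of T cell traffic, at 402 and 630 CPM. The exhaustion list was at 0.28 (14 of 18 higher, mean 0.11), with Ctla4, an inhibitory receptor, at 33.3 and 51.7 CPM. Cd38, with an estimated 59.6% of its vehicle level from free tumour RNA, was at 9.60 and 4.69 CPM. The cytotoxic list was at 0.04 (mean -0.10), with Prf1, perforin, at 19.2 and 15.6 CPM, and Gzmb, granzyme B, was at 49 and 11 UMIs (6.63 and 1.72 CPM, log2 -1.49), with 38.8% of its vehicle UMIs in 1 cell, and at -1.07 with the highest cell of each library left out. The S phase list was at 0.02 (mean -0.05), G2/M at -0.15, or -0.04 after subtraction of free tumour RNA, and interferon-stimulated genes at -0.07, or 0.01 at 2000 UMIs per cell. Ifngr2, a chain of the interferon gamma receptor, was at 164 and 311 CPM and Socs1, an inhibitor of cytokine signals, at 36.6 and 65.0 CPM. Among the lowest genes, Ctsl (90.3 and 45.8 CPM) and Dst (61.8 and 24.99 CPM) had an estimated 70.0% and 79.0% of their vehicle level from free tumour RNA. Free tumour RNA made up an estimated 6.92% of vehicle and 3.91% of RP-6306 CD8 T-like UMIs, and these estimates may be too high. The dissociation stress list summed to 3764 and 4367 CPM. Cluster T0 held most of the class in both libraries (1543 and 1569 cells), while T3, led by Ly6c2 among others, held 500 and 324 cells and T5 held 216 and 288 cells. Ly6c2 was itself lower in the class (log2 -0.33), and how far this sets the size of T3 was not tested. The gene lists were not computed within T0, T3 or T5, so a different mix of them cannot be told apart from a difference within them.

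CD4 T-like cells of the RP-6306 library also had a higher naive and memory list, at 0.26 (13 of 16 higher), with Il7r at 727 and 1341 CPM (0.88, 0.82 to 0.94). Zfp36, which destabilises cytokine transcripts, was at 123 and 278 CPM, and Socs1 and Socs3 at 44.2 and 96.4 and at 38.1 and 82.1 CPM. Zfp36 is also a member of the dissociation stress list, which summed to 4613 and 5785 CPM. The exhaustion list was at 0.10 (mean -0.26), or 0.31 for genes with at least 100 UMIs, the cytotoxic list at -0.03 (mean 0.12) and interferon-stimulated genes at -0.12, or 0.03 within cluster T1. Cluster T1 held most vehicle and T2 most RP-6306 cells, and within T1 alone the naive and memory list was at 0.31.

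Regulatory T-like cells (183 and 124) of the RP-6306 library had lower effector genes, at -0.42 (16 of 19 lower). Tnfrsf9, a costimulatory receptor of activated T cells, was at 1178 and 557 CPM (-1.08, -1.33 to -0.84), Icos at 884 and 523 CPM and Gzmb, which is not in this list, at 1558 and 723 CPM. Most vehicle cells lay in cluster T10 (159 and 41 cells) and most RP-6306 cells in T11 (24 and 83 cells). Tnfrsf9, Klrg1 and Gzmb are among the leading genes of T10 and not T11, and Foxp3 of T11 and not T10. The list was not computed within either cluster, so a different mix of them cannot be told apart from a difference within them. The dissociation stress list summed to 4994 and 6226 CPM, ribosomal protein genes to 27618 and 39944 CPM, endothelial markers to 130.5 and 206 CPM and tumour markers to 322 and 197 CPM. Interferon-stimulated genes were at 0.33 and G2/M genes at 0.23, or -0.24 as a mean over cells.

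In NK-like cells (411 and 143) the killing genes Gzmb (1022 and 1009 CPM) and Prf1 (358 and 317 CPM) had log2 intervals that included 0. The cytotoxic list was at -0.02, or -0.12 with size factors and -0.13 at 2000 UMIs per cell, and its mean of -1.14 came from Gzmd, Gzme, Gzmf and Gzmg, for which 83.8 to 97.7% of vehicle UMIs came from 1 cell. In this list 3 members had 0 UMIs in 1 library, and a floor of 3 UMIs there gave a mean of -0.78. Il7r was at 60.7 and 169 CPM and Klrc1, an inhibitory receptor chain, at 278 and 499 CPM. In these cells T cell markers summed to 847 and 1022 CPM, B cell markers to 176 and 108 CPM and neutrophil markers to 81.5 and 41.75 CPM. Free tumour RNA made up an estimated 8.89% and 4.57% of their UMIs. Interferon-stimulated genes were at 0.12 and G2/M genes at -0.13, or -0.39 without the UMI minimum.

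In B clusters 0 and 12 together, class II genes were at 0.13, with Cd74, the invariant chain, at 9316 and 12033 CPM (0.37, 0.36 to 0.38), and interferon-stimulated genes at 0.08, both within the central 95% of random lists. Btg2, an antiproliferative gene of the dissociation stress list, was at 360 and 715 CPM.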

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

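Of the tests in this part, those within single clusters, without the Ptprc-carrying subclusters, of free tumour RNA, of dilution by naive lymphocytes and of droplets with more than 1 cell among the Cdh5-high cells were chosen only after the data or the result were seen, as was the use of cluster and naming alternatives, and of a bound of 1.2-fold in place of 1.3-fold, for the CD4 T-like share.

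Interferon-stimulated genes were lower in the RP-6306 library in tumour-like cells (median log2 ratio -0.37) and in macrophage and monocyte-like cells (-0.65). In regulatory T-like cells the list was higher (0.33), and T cluster T6, led by interferon genes, held 179 vehicle and 290 RP-6306 cells. A different mix of tumour clusters 3, 6 and 7 is argued against by the list's median in the cluster where it was closest to 0 (-0.23). Lymphocytes caught with tumour cells are argued against by its median without the subclusters that carry Ptprc (-0.37). Finer tumour subclusters also differed in share, such as 1 with 23.8% of vehicle and 8.56% of RP-6306 tumour-like cells. The list was not computed within each of them, so a mix at that level stays open. In macrophage and monocyte-like cells the median stayed at -0.67 after subtraction of free tumour RNA, but in the cluster where it was closest to 0 it was 0.0447, so a different mix of clusters may account for part of that pattern. Macrophage clusters alone were at -0.89 (M0 -0.19, M3 -0.53) and monocyte clusters alone at 0.11 (M1 0.30, M2 0.0447). A response to RP-6306 and a difference between single tumours both stay open, since each group was 1 library.

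CD4 T-like cells were a higher and NK-like cells a lower share of named leukocytes in the RP-6306 library. Without any class, over all cells outside the tumour clusters, NK receptor genes per Ptprc UMI were 2.17-fold lower (95% interval 2.01 to 2.33), which argues against the assignment of cells as the whole cause of the NK difference. Cd4 UMIs per Cd8a and Cd8b1 UMI were 1.35-fold higher (1.26 to 1.44), an interval that includes the bound of 1.3 but lies above the 1.2 that assignment alone would allow. The log2 ratio of the CD4 T-like share was 0.84 with each cell named by its own marker score and between 0.73 and 1.91 under the other ways of clustering and naming, so assignment is argued against as its whole cause, while its size stays open. Dilution by naive lymphocytes would lower the NK-like and the macrophage and monocyte-like shares alike, and their log2 ratios differed by -1.53. With 1 class as the comparison, a part played by dilution in the NK-like difference stays open. The comparison does not bear on the CD4 T-like share, whose difference lay in cluster T2 (log2 ratio 2.09, T1 -0.01). Naive lymphocytes stay open as a source of that share, and the sort, the mouse and the treatment as sources of both.

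A pair of tumour subclusters with high Cdh5, which encodes VE-cadherin (chromosome 8, 104101625 to 104144511), held 9 of 2847 vehicle and 198 of 3106 RP-6306 tumour-like cells (0.316%, 0.145 to 0.599, and 6.37%, 5.54 to 7.29). Droplets with a leukocyte or endothelial cell are argued against, since the higher of the folds of Ptprc and Pecam1 over the remaining tumour-like cells was 0.284 (0.184 to 0.421). The remaining cells include the subclusters that carry Ptprc (146 and 101 CPM), which lowers the Ptprc fold. Against the other subclusters, at 3.41 to 6.53 CPM, Ptprc in the Cdh5-high ones was about alike, at 3.03 and 4.99 CPM. Cdh5 was also 2.05-fold higher in the remaining RP-6306 cells (1.90 to 2.22). This lies around the bound of 2 set for a shift of the whole library, so the test does not decide whether such a shift plays a part. Cdh5 was at 110 and 105 CPM in the pair and at 11.8 to 24.1 CPM in the other subclusters. The pair was picked by its Cdh5 level, so this gap is no separate evidence. Clusters mostly of 1 library may be that library, a clone within 1 tumour or an effect of treatment, and these stay open.

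An unnamed cluster with both macrophage and tumour genes, in none of the classes compared but among the cells of the Cd4 and NK receptor quotients, held 1 vehicle and 99 RP-6306 cells. Krt18 was at 356 CPM (354 in RP-6306 tumour-like cells) and Lyz2 at 503 CPM (5594 in RP-6306 macrophage and monocyte-like cells). Its cells were shallow, with a median of 4111 UMIs, beside 31956 in RP-6306 tumour-like and 7559 in RP-6306 macrophage and monocyte-like cells.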

How the results depend on the processing

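Alternatives that take only some clusters, leave out subclusters, subtract tumour RNA, use the first naming rule, count mixed clusters, thin to 10000 UMIs or leave out the cell with the most UMIs of a gene were chosen after seeing the data, and the others before the data were examined. No paired analysis was possible because each group had 1 library. Among the alternatives set beforehand, 371 list medians were the same, 14 moved and 2 reversed, and for shares 76 were the same, 9 moved and 2 reversed. For named genes 836 ratios were the same, 130 moved and 3 reversed. Among those added later, 113 list medians were the same, 33 moved and 19 reversed, 17 shares were the same, 3 moved and 1 reversed, and 720 gene ratios were the same, 265 moved and 23 reversed. A gene counted as reversed where its sign changed and its counting interval in all cells excluded 0, so sign changes of other genes are among those that were the same or moved. For all changes below the cause was not tested. Some classes held few cells, such as 143 NK-like and 124 regulatory T-like cells in the RP-6306 library, which limits the depth behind their values.

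For log2 ratios of shares, naming each cell by its own marker score gave 0.0235 for B-like, 0.088 for CD8 T-like, 0.84 for CD4 T-like, -0.25 for regulatory T-like, -1.22 for NK-like, -0.41 for macrophage and monocyte-like, 0.34 for all T-like and 0.14 for tumour-like cells. The first naming rule gave 0.01 for CD8 T-like, 1.91 for CD4 T-like and -1.11 for regulatory T-like cells. A mitochondrial maximum of 10% gave 0.64 for CD4 T-like cells, and mixed leukocyte clusters in the total gave 0.22 for all T-like cells. The tumour-like share was at 0.0551 with at least 1000 UMIs and at 0.0373 with each library clustered on its own, which gave no ratio for gamma delta T-like cells because none were named in the RP-6306 library. With doublets kept the share of tumour-like cells in S or G2/M was at 0.54.

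For list medians, size factors gave -0.12 for the NK cytotoxic list. A pseudocount of 10 CPM gave 0.34 for G2/M, -0.17 for interferon-stimulated and -0.18 for interferon gamma genes in tumour-like cells, and -0.45 for interferon-stimulated genes and 0.50 for chemokines in macrophage and monocyte-like cells. A minimum of 100 UMIs gave 0.31 for CD4 exhaustion, and of 1 UMI -0.39 for NK G2/M. With doublets kept interferon-stimulated genes in macrophage and monocyte-like cells were at -0.82. The mean over cells gave -0.24 for regulatory T G2/M and -0.25 for interferon gamma genes in macrophage and monocyte-like cells. At 2000 UMIs per cell the CD8 interferon-stimulated list was at 0.0104, the NK cytotoxic list at -0.13, and in macrophage and monocyte-like cells checkpoint ligands were at 0.22, chemokines at 0.50 and hypoxia at 0.0572. Subtracting tumour RNA gave -0.0366 for CD8 G2/M, and cluster T1 alone gave 0.0276 for CD4 interferon-stimulated genes.

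Within tumour cluster 3 the PKMYT1 pathway was at 0.10, S phase at 0.27, G2/M at 0.0464, hypoxia at 0.0432, the unfolded protein response at 0.0066 and histones at -0.10. Within cluster 6 the PKMYT1 pathway was at 0.0382, S phase at 0.0225, G2/M at 0.0022, interferon gamma genes at -0.17 and histones at 0.27. Within cluster 7 the PKMYT1 pathway was at 0.13, S phase at 0.25, G2/M at 0.0305, interferon-stimulated genes at -0.23, chemokines at -0.21 and histones at -0.23.

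In macrophage clusters alone the alternative macrophage list was at 0.31, MHC class II at -0.11, interferon-stimulated genes at -0.89, interferon gamma genes at -0.82 and chemokines at 0.49. In monocyte clusters alone the alternative list was at 0.14, interferon-stimulated genes at 0.11, interferon gamma genes at 0.49, checkpoint ligands at 0.19, chemokines at 0.26 and hypoxia at 0.14. Cluster M0 gave 0.11 for the alternative list, -0.16 for MHC class II, -0.19 for interferon-stimulated genes, 0.36 for checkpoint ligands, 0.27 for chemokines and 0.0888 for hypoxia. Cluster M1 gave -0.0106 for the alternative list, 0.30 for interferon-stimulated and 0.69 for interferon gamma genes, 0.28 for chemokines and 0.31 for hypoxia. Cluster M2 gave 0.60 for the inflammatory and -0.35 for the alternative list, 0.0447 for interferon-stimulated and 0.38 for interferon gamma genes, 0.23 for checkpoint ligands, 1.00 for chemokines and 0.19 for hypoxia. Cluster M3 gave -0.17 for the inflammatory and 0.18 for the alternative list, -0.20 for interferon gamma genes and -0.0737 for chemokines.

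Genes that reversed were, within tumour cluster 3, Hist1h1d (-0.0078) and Hist1h4c (-0.10), and within cluster 7 Hist1h1d (-0.33), Pkmyt1 (-0.17), Cd80 (-0.0381) and Elovl5 (0.0051). Within cluster 6 these were Pkmyt1 (-0.15), Wee1 (-0.31), Tgtp1 (0.0568), Tgtp2 (0.13), Ulbp1 (-0.0092) and Herc3 (0.17). In monocyte clusters they were Igfbp4 (-0.31), Hist1h3c (-1.21), Mrc1 (-2.26), Hdac9 (-0.24), Rsad2 (0.41), Ifit2 (2.102), Cxcl10 (0.84), Ciita (0.0743), Cmpk2 (0.43), Gbp2 (0.37) and Ndrg1 (0.30). With doublets kept Ccl5 in tumour-like cells was at 0.0739, and at 2000 UMIs per cell Herc3 in tumour-like cells was at 0.0368 and Vegfa in macrophage and monocyte-like cells at 0.0012.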

Other observations

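Fkbp5, a target gene of the glucocorticoid receptor, was among the genes with the highest ratios in 2 lymphocyte classes of the RP-6306 library. It was at 39.0 and 80.2 CPM in CD4 T-like cells (log2 1.02, interval 0.78 to 1.3035) and at 34.4 and 75.1 CPM in B clusters 0 and 12 (1.10, 0.92 to 1.34). In CD8 T-like cells, looked up after these values were seen, Fkbp5 was at 42.6 and 52.8 CPM. Slc15a2, a peptide transporter, was at 107 and 229 CPM in the B clusters.

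Cdk8 was lower in the RP-6306 library in CD8 T-like (1720 and 1059 CPM) and CD4 T-like (1768 and 978 CPM) cells and in B clusters 0 and 12 (1320 and 762 CPM). Cdk8 was also among the leading genes of an unnamed cluster with low UMIs, which held 10.7% of vehicle and 1.77% of RP-6306 cells. Estimated free tumour RNA was higher in the vehicle library too: 6.92% and 3.91% in CD8 T-like cells, 8.39% and 4.73% in CD4 T-like cells, and 9.34% and 5.40% in the B clusters. Free RNA from other sources was not estimated in these classes, so lower Cdk8 expression cannot be told apart from less free RNA. The unnamed cluster with T and B cell genes mixed that shares leading genes with regulatory T cluster T10 held 465 vehicle and 184 RP-6306 cells.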
